A study of Mus musculus with 6 samples.

How the data were processed

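Messenger RNA was measured by sequencing in 6 libraries of wild-type mouse retina, 1 for each of the ages E16.5, P1, P3, P7, P14 and P28. Per the labels' protocols, fresh retinas were dissected in cold buffer, total RNA was extracted with Trizol, messenger RNA was purified on magnetic beads and made into double-stranded cDNA, and the fragmented cDNA was built into libraries with an Illumina kit for ChIP DNA. The labels give the strain as 129/Sv; C57/BL6J and give neither the sex of the mice nor the number pooled per library. Per the submitters' processing notes, bcl2fastq 2.17.1.14 was used and the genome build was mm9; the aligner, the counting tool, the gene annotation, the treatment of reads that map to several places and the strand used in counting are not given in the sources used here.

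The authors deposited 1 table with an RPKM value for each of 30042 genes and 6 ages, per the file headers, and no read counts were used as the starting point. RPKM divides a gene's reads by its length and by the number of reads of the library, so that long and short genes and deep and shallow libraries are put on 1 scale, and it does not correct for a few abundant genes taking up reads. The sum of RPKM over all genes went from 179379 at E16.5 to 133675 at P28, and the 10 highest genes held between 4.13% and 10.8% of it. No gene symbol occurred more than once, 5754 genes were at 0 in every library, and 0 columns of sample values were left unused. No coordinates are given, because the table holds none and the reference annotation at hand is of another build than mm9.

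The depth of each library was read from the values. Low values of a gene fall on whole multiples of what 1 read is worth, and the ratio of these steps between libraries gives their relative depth, while reference transcript lengths give the absolute depth, as an estimate. Of low values (under 0.3 RPKM) of genes with a single reference length, between 62.8% and 68.0% were whole numbers of reads within a tolerance of 0.05. The estimated totals were lowest at P1 (12746477 reads) and highest at P14 (28796552 reads). At these depths 1 read in a gene of 2 kb is worth between 0.0174 and 0.0392 RPKM. Because whole reads were recovered for only part of the genes, no test on counts was run. For the deiodinases and Opn1mw the recovered reads give 95% Poisson intervals, and 95% intervals of ratios come from the exact binomial distribution; all of them cover counting error only, since PCR copies are not independent molecules.

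Values were analysed as log2(RPKM + 1), which understates changes of genes near or below 1 RPKM. Genes whose highest value was at least 1 RPKM were tested, 15272 in all. The age trend was a linear slope over age order from 1 to 6, in log2 units per step, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend=TRUE), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 4 residual degrees of freedom, its spread holds both library noise and departures from a straight line, and separate retinas of 1 age were not compared. Curvature was the quadratic coefficient after the linear one, with 3 residual degrees of freedom. Differences between 2 ages have no test: a gene counts as higher or lower at a difference of at least 1 on the log2 scale with the higher value at least 1 RPKM. For Dio2 and Dio3, Pearson's r and Spearman's rho with age order were tested by exact permutation, two-sided, as a family of 4 relations.

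Gene lists, tests, the rule for naming genes and most alternatives were fixed before the data were examined. The 27 lists were thyroid hormone signalling, cone photoreceptor, rod photoreceptor, photoreceptor precursor transcription factors, visual cycle, retinal progenitor, cell cycle, retinal ganglion cell, amacrine cell, horizontal cell, bipolar cell, Muller glia, astrocyte, endothelial and pericyte, microglia and macrophage, pigment epithelium and melanocyte, lens, erythroid, oligodendrocyte and optic nerve, extraocular muscle, cornea and surface epithelium, synapse, oxidative phosphorylation, glycolysis, cell death, housekeeping and sex-linked genes. They describe whole tissue and do not count cells, and a few genes belong to more than 1 list, such as Rlbp1 (visual cycle and Muller glia) and Pax6 (progenitor and amacrine). The 26 lists with at least 3 tested genes were compared with all other tested genes by limma's camera with a preset correlation of 0.01, adjusted over the lists; called were 11 lists upward and 5 downward. With a correlation estimated from the 6 libraries 0 lists were called, 3 had an unadjusted p under 0.05, and the lowest adjusted p was 0.102. For differences between 2 ages, the median of a list was placed among 10000 random lists of the same size matched on mean expression.

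Genes named in the text were chosen by a rule of 6 parts. It takes every measured gene of the thyroid hormone list and of the opsins; the 10 highest and 10 lowest slopes among called genes that move the same way in all 5 steps; the 6 largest gains and 6 largest losses between E16.5 and P28; the 4 largest gains and 4 largest losses of each step; the 6 most negative and 6 most positive curvature coefficients, as values where none is called; and from each list the 4 called genes with the steepest slopes plus up to 2 called genes that move against the majority, or where none is called the 2 with the highest mean. RIKEN, Gm, LOC and microRNA models are passed over in the parts that are not lists. Some genes that the rule takes are not reported here. Gngt2, as an example of the cone list, and the genes taken from lists added later were chosen after their values were seen.

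Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 RPKM, rescaling by median-of-ratios factors or to a common total without the 50 genes of highest value, leaving out each age in turn, age as log2 days after conception with birth as day 19, limma without the mean trend, an exact Spearman test, an estimated camera correlation and a size rule of 2 log2 units. Median-of-ratios rescaling moved the log2 level of a library by -0.10 at E16.5 to 0.19 at P28, and the common total by -0.26 at E16.5 to 0.18 at P28, so directions close to these shifts depend on the scaling. After the data were seen, a term for the 2 forms of library title and the subtraction of a share of the E16.5 values from P28 were added. The trend fit was tested on simulated libraries of the 15272 genes with known slopes: at slopes of 0.25, 0.5 and 1 log2 units per step it recovered 23.9%, 82.1% and 98.5% of changed genes when 200 genes were changed, with 8 false calls (5.56% of calls). When 6872 genes were changed by 0.5 per step it recovered 96.4% with 2.97% false calls. That slope is steeper than the median slope of the called genes, 0.29 for those that rose and -0.27 for those that fell. Of 50 simulated lists without a change 3 had a camera p under 0.05. The 200 changed genes were drawn from genes with a mean log2(RPKM + 1) above 1, so their recovery rates do not cover genes of lower mean. The simulated genes had straight slopes and independent noise. The simulations therefore cannot show how the fit treats curved changes, or how camera treats lists whose genes vary together. Tables and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.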

Results

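The series profiled messenger RNA of the whole retina of wild-type mice from late embryonic life to young adulthood. Its title concerns cone photoreceptor loss in mice that lack type 3 deiodinase, the enzyme that inactivates thyroid hormone, and the effect of also removing type 2 deiodinase, the enzyme that activates it. The 6 libraries analysed here are all wild type, and each stands for 1 age: embryonic day 16.5 (E16.5) and postnatal days 1, 3, 7, 14 and 28 (P1 to P28). The values are RPKM, reads scaled to the length of the gene model and to the size of the library, for 30042 genes, of which 15272 reached 1 RPKM at some age and were tested. Relative to P1, the shallowest library, the depth read from the steps between low values was 1.13 at E16.5, 1.86 at P3, 1.83 at P7, 2.26 at P14 and 1.01 at P28. With 1 library per age no pair of ages could be tested against each other, so a difference between ages is given as a value, and the test asked whether a gene followed a straight line over the 6 ages. Its p-values reflect the spread around that line between libraries of different ages, not between replicate retinas.

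Dio2, the gene of the activating deiodinase, and Dio3, the gene of the inactivating deiodinase, moved in opposite directions. Dio2 rose with age (slope 0.72 ± 0.14 log2 units per age step, SE, adjusted p = 0.00582), from 0.0595 RPKM at E16.5 and 0.159 at P3 to 0.552 at P7, 7.35 at P14 and 9.01 at P28. Its value at P14 was 13.3 times that at P7, with a 95% counting interval of 10.5 to 17.0. Dio3 fell with age (slope -0.66 ± 0.17, adjusted p = 0.0166), from 16.1 RPKM at E16.5 to 4.12 at P1, 0.857 at P3, 0.229 at P7 and 0.204 at P14. The ratio of Dio3 to Dio2 was 271 at E16.5, 30.5 at P1, 5.38 at P3, 0.415 at P7, 0.0278 at P14 and 0.0926 at P28.

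At P28 Dio3 was listed at 0.834 RPKM, 4.08 times its P14 value (95% counting interval 1.86 to 9.43), from an estimated 20 reads against 11. Many genes high at E16.5 and near 0 at P14 left a trace in the P28 library, with a median share of 2.21% of the E16.5 value. The source of this trace is not settled. Subtracting that share of the E16.5 value of Dio3 left 0.479 RPKM at P28, still above the P14 value. Before subtraction, the 95% counting interval of the P28 value was 0.510 to 1.29 RPKM. The correlation of Dio2 with age order was r = 0.89 (exact permutation p = 0.00278, two-sided, adjusted over 4 relations 0.00556) and Spearman's rho was 1 (exact p = 0.00278, adjusted 0.00556), the smallest p that 6 libraries allow. For Dio3 r was -0.82 (exact permutation p = 0.0278, adjusted 0.0370) and rho was -0.83 (exact p = 0.0583, adjusted 0.0583). Without E16.5 and P28, the ages farthest from the middle of the series, r was 0.85 for Dio2 and -0.91 for Dio3. The calls for the fall of Dio3 depended on the setting. Without E16.5 the slope was -0.36 (adjusted p = 0.136) and r was -0.67 (exact p = 0.167), and with age in log2 days the slope did not pass (adjusted p = 0.0744). The correlation also missed the threshold without P1 (exact p = 0.0833), P3 (0.0583), P7 (0.0750) or P14 (0.108), with a pseudocount of 0.1 (0.0528) or with median-of-ratios rescaling (0.05). The correlation of Dio2 missed it without P3 (r = 0.90, exact p = 0.0667). Reads of Dio3 could not be separated from those of its antisense partner, because the strand used in counting is not given in the sources used here. Dio1, the gene of the remaining deiodinase, had 0 or 1 estimated read at every age.

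**Figure D1:**
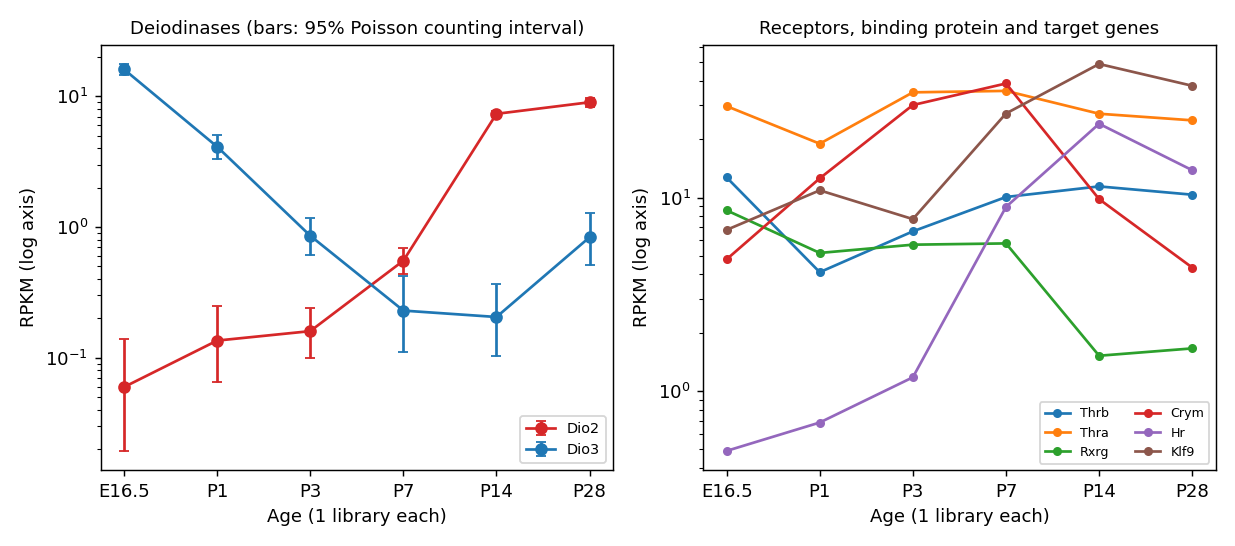
RPKM on a log axis against age, with 1 library per age; the left panel shows Dio2 and Dio3 with 95% Poisson counting intervals, and the right panel shows 6 other genes of the thyroid hormone list. Dio2 lay at 0.0595 RPKM at E16.5 and 9.01 at P28, Dio3 at 16.1 and 0.834, and the lines crossed between P3 and P7.

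The wider list of thyroid hormone signalling genes held 20 tested genes, of which 7 rose, 4 fell and 9 did not pass the test, with the same 7 and 4 when adjusted over the list alone. Hr, a corepressor that is a direct target of thyroid hormone receptors, rose from 0.49 RPKM at E16.5 to 24.1 at P14 (slope 0.87 ± 0.14, adjusted p = 0.00336), 49.1 times the E16.5 value. Klf9, another receptor target, rose from 6.80 to 49.0 RPKM over the same ages (slope 0.56 ± 0.11, adjusted p = 0.00545). The hormone carrier Ttr, the amino acid and hormone transporter Slc7a8, the organic anion transporter Slco1c1 and the sulfotransferase Sult1a1 also rose, with slopes of 0.78, 0.61, 0.23 and 0.27. Besides Dio3, the retinoid X receptor Rxrg was among the genes that fell (8.58 RPKM at E16.5 to 1.52 at P14, slope -0.37). The receptor genes did not pass the test: Thrb was at 12.7 RPKM at E16.5, 4.11 at P1 and 11.4 at P14, and Thra ranged from 18.97 to 35.6 RPKM. The slope of Thrb was 0.09, and without E16.5 it was 0.30 and passed (adjusted p = 0.0275). Crym, which encodes a cytosolic thyroid hormone binding protein, went from 4.79 RPKM at E16.5 to 38.9 at P7 and 4.34 at P28, with a slope of -0.03.

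As a list these genes were shifted upward relative to the other genes (limma's camera, adjusted p = 0.0395), with adjusted p = 0.468 with an estimated correlation, and the upward call was also lost without P1 (0.0676), P7 (0.0505) or P14 (0.0530), with median-of-ratios rescaling (0.0792), with age in log2 days (0.0633) and with a term for the form of library title (0.0763). Among single calls that depended on 1 library was Slco1c1 (adjusted p 0.0639 without P1 and 0.0617 without P28).

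Over all tested genes the age trend called 2326 genes that rose (15.2%) and 4571 that fell (29.9%), with limma and Benjamini-Hochberg adjustment. The split moved with the scaling between libraries: median-of-ratios rescaling gave 3110 that rose and 3396 that fell, and a common total without the 50 highest genes gave 3272 and 2720. No gene called both as deposited and under either rescaling changed its sign. Of the tested genes 407 rose at every step and 908 fell at every step, against 21.2 expected for each from random orders. Among the genes that rose at every step the steepest were Prph2 and Rom1, structural proteins of photoreceptor outer segment discs, the rhodopsin kinase Grk1, the vesicular glutamate transporter Slc17a7, the guanylate cyclase activator Guca1a and the complexin Cplx4. Prph2 went from 5.90 RPKM at E16.5 to 848 at P28 (slope 1.49 ± 0.11, adjusted p = 0.00148). Rgs9bp, an anchor of the phototransduction regulator Rgs9, the guanylate cyclase Gucy2e and the rod protein Reep6 were also among the 10 steepest, with slopes of 1.26 to 1.27.

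The steepest among genes that fell at every step were the tubulin genes Tubb2b and Tubb2a-ps2, which share near-identical sequence so that their reads are uncertain, followed by the Notch target Nrarp, the neuronal membrane protein Islr2, the Myc family gene Mycl1 and the growth cone protein Gap43. Tubb2b went from 339 RPKM at E16.5 to 7.70 at P28 (slope -1.10 ± 0.13, adjusted p = 0.00165). Ctxn1, Marcksl1, Rnd3 and Pdzrn3 followed with slopes of -0.84, -0.81, -0.80 and -0.80. Among genes that rose, the largest step lay between P7 and P14 for 860 genes (37.0%) and between P3 and P7 for 680 (29.2%). Among genes that fell, it lay between P7 and P14 for 1302 genes, between P1 and P3 for 1284 and between P3 and P7 for 1096. The libraries carried 2 forms of title, shared by E16.5, P1 and P28 on one side and by P3, P7 and P14 on the other, and with a term for these sets, added after the data were seen, 2414 genes rose and 4819 fell. Without P14 the counts dropped to 1538 that rose and 2953 that fell.

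The cone opsin genes came on at different ages. Opn1sw, the short-wavelength cone opsin, rose early, from 4.03 RPKM at E16.5 to 35.3 at P1 and 112 at P28 (slope 0.73 ± 0.15, adjusted p = 0.00666). Opn1mw, the middle-wavelength cone opsin, rose late, from 0.0539 RPKM at P3 and 0.794 at P7 to 39.5 at P14 (slope 1.16 ± 0.26, adjusted p = 0.0104). Its P14 value was 49.8 times that at P7, with a 95% counting interval of 34.5 to 74.6, and its slope did not pass without P28 (adjusted p = 0.0617).

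**Figure D2:**
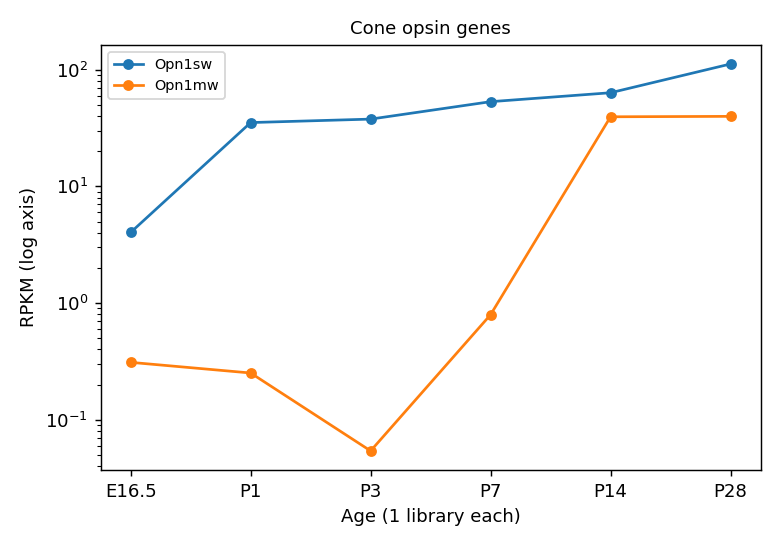
RPKM of the cone opsin genes Opn1sw and Opn1mw on a log axis against age, with 1 point for the 1 library of each age. Opn1sw was already at 35.3 RPKM at P1, whereas Opn1mw reached 39.5 RPKM only at P14.

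Of 17 tested genes of the cone list 12 rose, 0 fell and 5 did not pass, with 12 also when adjusted over the list alone. Values of whole retina do not show which cells a transcript came from, so these rises cannot be assigned to cones alone. Guca1a rose from 0.95 RPKM at E16.5 to 234 at P28, the potassium channel subunit Kcnv2 from 1.20 to 108, and the cone arrestin Arr3 from 0.612 to 61.9. Gngt2, a cone transducin subunit that did not pass, was at 7.48 RPKM at E16.5, 21.9 at P3 and 5.36 at P28. The cone list was shifted upward (camera adjusted p = 2.1e-06), with adjusted p = 0.102 with an estimated correlation. All 26 tested rod genes rose, and all 26 when adjusted over the list alone (camera adjusted p = 2.3e-18, and adjusted p = 0.323 with an estimated correlation). The rise of Nr2e3, 1 of these genes, was not called without E16.5 (slope 0.36 against 0.96, adjusted p = 0.339), P1 (0.0803) or P14 (0.0802), without a filter (0.0721) or with age in log2 days (0.130). The rod transducin Gnat1 rose to 3046 RPKM at P28 (slope 1.70 ± 0.40), the phosphodiesterase subunit Pde6a from 1.13 to 214 and the exchanger Slc24a1 from 0.836 to 179. Gnat1 was higher at E16.5 (16.5 RPKM) and P1 (19.95) than at P3 (5.32), and without P28 its adjusted p was 0.0763.

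The visual cycle list, whose enzymes and carriers regenerate the light-absorbing retinoid, rose in 10 of 13 tested genes, 10 also when adjusted over the list alone, and fell in 0. The retinol dehydrogenases Rdh8 and Rdh12 rose from 0.286 to 58.3 RPKM and from 0.551 to 43.5 RPKM between E16.5 and P28, and the retinoid transporter Abca4 from 0.562 to 60.2. This list was shifted upward (camera adjusted p = 1.3e-05, and adjusted p = 0.102 with an estimated correlation). It shares Lrat, Rgr and Rpe65 with the pigment epithelium list, of whose 8 tested genes 5 rose. Of 12 tested transcription factors of photoreceptor precursors, 7 fell, 1 rose and 4 did not pass, with the same counts when adjusted over the list alone. Foxn4 fell from 51.7 RPKM at E16.5 to 0.0706 at P14 and Olig2 from 26.1 to 0, while Crx, the cone-rod homeobox factor, rose from 44.5 RPKM at E16.5 to 320.3 at P7 (slope 0.48 ± 0.14, adjusted p = 0.0236). The precursor list was shifted downward (camera adjusted p = 0.0499, and adjusted p = 0.571 with an estimated correlation). That shift was not called without P1 (0.0676) or P28 (0.0854), with a pseudocount of 0.1 (0.0702) or with age in log2 days (0.0501), and the rise of Crx was not called without E16.5 (0.179), P1 (0.0736) or P14 (0.0611).

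Progenitor and cell cycle genes fell over the series, but differed in the first step: between E16.5 and P1 the median difference was 0.19 log2 units over the cell cycle list (percentile 99.3 of matched random lists) and -0.38 over the progenitor list (percentile 0.92). Of 16 tested progenitor genes 15 fell and 0 rose, 15 also when adjusted over the list alone, and of 30 cell cycle genes 29 fell, or 30 when adjusted over the list alone. The cyclin Ccnd1 went from 558 RPKM at E16.5 to 671 at P1 and 5.77 at P14, and the growth factor Fgf15 fell from 248 at E16.5 to 0.307 at P14, the Notch target Hes5 from 90.9 to 2.95 and the receptor Notch1 from 47.2 to 3.28. The proliferation marker Mki67 went from 99.8 RPKM at E16.5 to 181 at P1, 81.9 at P3, 4.63 at P7 and 0.309 at P14, and the topoisomerase Top2a from 36.1 at E16.5 to 43.4 at P1 and 0.156 at P14. Camera placed both lists below the other genes (progenitor, adjusted p = 1.3e-05, and adjusted p = 0.390 with an estimated correlation; cell cycle, adjusted p = 1.0e-08, and adjusted p = 0.504 with an estimated correlation). At P28 the values were again above those at P14, with 2.505 RPKM for Mki67, 7.03 for Fgf15 and 13.7 for Ccnd1. Many other transcripts high at E16.5 also left a trace of unsettled source in that library. Without E16.5 the fall of Fgf15 was not called (adjusted p = 0.0944).

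**Figure D3:**
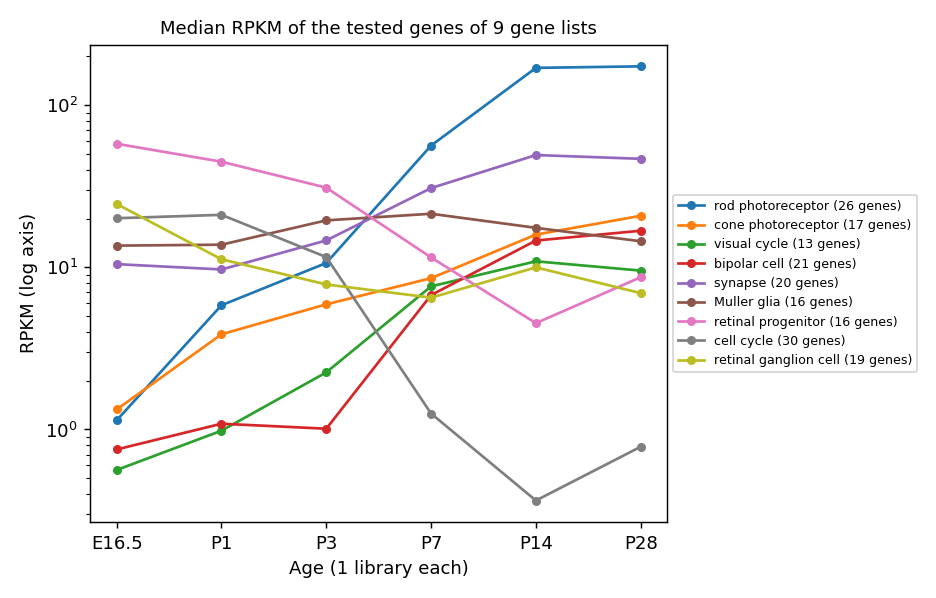
Median RPKM of the tested genes of 9 gene lists on a log axis against age, with 1 library per age. The rod median went from 1.139 RPKM at E16.5 to 174 at P28 and the cell cycle median from 21.1 at P1 to 0.364 at P14, with 0.782 at P28.

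Among neurons of the inner retina, ganglion cell genes fell and bipolar cell genes rose. Of 19 tested ganglion cell genes 13 fell, 2 rose and 4 did not pass, with the same counts when adjusted over the list alone. Gap43 fell from 365 RPKM at E16.5 to 13.9 at P28 (slope -0.91 ± 0.10), the homeobox factor Dlx2 from 10.4 to 0.246, and Atoh7, the factor that specifies ganglion cells, from 195 at E16.5 to 21.1 at P1 and 0.551 at P14. Nefh, the heavy neurofilament, and Thy1, a surface glycoprotein, rose instead, from 1.66 to 21.9 RPKM and from 9.94 to 52.4. The ganglion cell list was shifted downward (camera adjusted p = 0.0354, and adjusted p = 0.743 with an estimated correlation), which was not called without E16.5 (0.345) or with age in log2 days (0.130). Atoh7 was not called without E16.5 (0.232), P1 (0.0644) or P14 (0.0775). Of 21 bipolar cell genes 16 rose and 2 fell, with the same counts when adjusted over the list alone (camera adjusted p = 2.9e-07, and adjusted p = 0.384 with an estimated correlation). Grm6, the glutamate receptor of ON bipolar cells, rose from 0.138 RPKM at P3 to 28.4 at P7, Lrtm1 from 1.08 at P7 to 33.7 at P14 and Gpr179 from 1.01 at P3 to 28.0 at P14. Irx5 and Irx6, homeobox factors of bipolar cells, fell, with slopes of -0.64 and -0.16, and Irx6 was called neither under the rescalings (adjusted p 0.106 and 0.202) nor without E16.5 (0.189), P14 (0.103) or P28 (0.114).

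Of 12 tested amacrine cell genes 7 rose and 3 fell, and 8 rose when adjusted over the list alone. The glycine transporter Slc6a9 rose from 3.62 RPKM at E16.5 to 34.9 at P28, the GABA-synthesising enzyme Gad1 from 1.53 to 15.7 and the inhibitory vesicle transporter Slc32a1 from 9.02 to 36.5, while the specification factors Ptf1a and Barhl2 fell from 24.8 to 0.102 and from 24.1 to 5.64. The amacrine list was shifted upward (camera adjusted p = 0.0354, and adjusted p = 0.390 with an estimated correlation), which was not called without E16.5 (0.0631) or with median-of-ratios rescaling (0.0792). Of 7 horizontal cell genes 3 rose and 3 fell, also when adjusted over the list alone. The calcium-binding protein Calb1 went from 0.238 to 3.77 RPKM and Onecut2 from 9.37 to 1.32. Camera made no call (adjusted p = 0.793), and the median slope of 0.03 and the mean of -0.06 differed in sign.

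Synaptic genes rose in 16 of 20 tested cases and fell in 0, with 16 also when adjusted over the list alone (camera adjusted p = 2.2e-10, and adjusted p = 0.363 with an estimated correlation). Slc17a7 rose from 1.75 RPKM at E16.5 to 230.2 at P28, Cplx4 from 1.53 to 133 and the calcium channel subunit Cacna1f of photoreceptor terminals from 0.384 to 29.5. Of 16 Muller glia genes 9 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.00581, and adjusted p = 0.323 with an estimated correlation). The water channel Aqp4 went from 0.392 RPKM at P7 to 16.2 at P14, clusterin (Clu) from 4.87 to 32.4 and the retinoid carrier Rlbp1 from 4.08 at E16.5 to 84.9 at P14, while the retinoic acid-degrading enzyme Cyp26a1 and vimentin (Vim) fell, with slopes of -0.78 and -0.37. Aqp4 was not called without P28 (adjusted p = 0.0627).

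Genes of glycolysis rose in 6 of 19 tested cases and fell in 2, with the same counts when adjusted over the list alone (camera adjusted p = 0.00517, and adjusted p = 0.571 with an estimated correlation; 0.0854 without P28). The aldolase Aldoc rose from 1.55 RPKM at E16.5 to 44.1 at P28, the enolase Eno2 from 5.14 to 60.8 and the hexokinase Hk1 from 12.1 to 48.2, while the glucose transporter Slc2a1 fell from 179.5 to 42.0 and was not called without E16.5 (adjusted p = 0.0820). Ldhb, a lactate dehydrogenase subunit, fell from 56.6 to 23.7 RPKM. That call was lost under the rescalings (limma, adjusted p = 0.0537 and 0.0505) and without E16.5 (0.0880) or P14 (0.0522). Gapdh, Pgk1 and Pgam1 were at 4.71, 4.64 and 2.15 RPKM at E16.5, against 173 for Aldoa. How reads that map to several places were treated is not given, so these low values are uncertain. Gapdh and Pgk1 are also in the housekeeping list. Of 22 genes of oxidative phosphorylation 0 rose and 2, Cox5b and Cox4i1, fell over all genes, with 0 when adjusted over the list alone. Neither fall was called under the rescalings (adjusted p of 0.0589 and 0.1003 for Cox5b, 0.113 and 0.188 for Cox4i1), and camera made no call (adjusted p = 0.629; median slope 0.00, mean -0.02).

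Of 14 cell death genes 10 fell and 1 rose, with 12 and 1 when adjusted over the list alone. The initiator caspase Casp8 fell from 2.16 RPKM at E16.5 to 0.212 at P28. The list was shifted downward (camera adjusted p = 0.0221, and adjusted p = 0.467 with an estimated correlation). Of 14 housekeeping genes 7 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.472). Actb, beta-actin, fell from 519 to 75.9 RPKM (slope -0.57 ± 0.07, adjusted p = 0.00194) and Ywhaz, a signalling adaptor, from 83.9 to 29.5, and both kept their calls under the rescalings, whereas Hprt, a purine salvage enzyme, rose from 10.04 to 25.7. Hprt was not called without P28 (adjusted p = 0.0767).

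Lists for cell types outside the neural retina differed in how many genes were called. Of 15 tested lens genes 1, Cryab, rose and 0 fell, with 0 when adjusted over the list alone, and Cryab was not called without P1 (adjusted p = 0.0530) or P28 (0.0574). Most lens crystallins were high at E16.5 and close to 0 from P3 to P14: Cryaa was at 23.7 RPKM at E16.5, 13.0 at P1, 0 at P3, 0.0360 at P7, 0.351 at P14 and 20.7 at P28. Camera made no call for the lens list (adjusted p = 0.754), but called it downward without P28 (0.00963). No erythroid gene of 5 tested was called (camera adjusted p = 0.918), and the alpha globin genes Hba-a1 and Hba-a2, whose reads are uncertain between copies, stood at 91.7 and 68.5 RPKM at E16.5 and at 0.753 and 0.924 at P1. Of 8 pigment epithelium genes 5 rose, also when adjusted over the list alone, among them Rgr (0.428 to 13.4 RPKM) and Rpe65 (0.108 to 3.00), with camera adjusted p = 0.00188 and adjusted p = 0.323 with an estimated correlation. Rpe65 was not called without P28 (0.0674). In the P28 library, where these were highest, Cryaa was also at 20.7 RPKM.

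Of 10 endothelial and pericyte genes 3 rose, also when adjusted over the list alone: the vascular receptor Flt1 (0.215 to 3.51 RPKM), the junction protein Esam (0.432 to 2.65) and the pericyte gene Rgs5 (0.593 to 7.88), each between E16.5 and P28. The list was lower at P28 than at P14, by a median log2 difference of -0.82 (percentile 0), and Rgs5 was at 22.5 RPKM at P14. The P14 and P28 libraries also differ in title form. Camera called this list upward (adjusted p = 0.0354, and adjusted p = 0.571 with an estimated correlation), but not without E16.5 (0.0822) or P14 (0.176), with median-of-ratios rescaling (0.0930), with age in log2 days (0.0685) or with the title term (0.0591), and Rgs5 was not called without E16.5 (0.0779). Of 8 microglia genes 2 fell, also when adjusted over the list alone, the lysosomal protein Cd68 from 3.41 to 0.496 RPKM and the adaptor Tyrobp from 1.58 to 0 (camera adjusted p = 0.472), and Tyrobp was not called without P28 (0.0616). Of 6 astrocyte genes 2 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.271), of 4 oligodendrocyte genes 1, Mog, fell (0.472; Mog was not called without P28, adjusted p = 0.0740), and of 3 surface epithelium genes 1, Krt18, rose and 1, Krt15, fell (0.991), or 2 fell when adjusted over the list alone. The single tested gene of extraocular muscle, Acta1, ranged from 0.473 to 2.10 RPKM and was not called.

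Sex-linked genes shifted between P3 and P7. Xist, the RNA that coats the inactive X chromosome of females, was at 87.4, 145 and 174 RPKM at E16.5, P1 and P3. At P7, P14 and P28 it was at 0.845, 0.870 and 2.06 RPKM. Its slope over age order was -1.42 ± 0.37 (limma, adjusted p = 0.0166). The labels do not give the sex of the mice, so an age trend of Xist cannot be told apart from a change in sex. The Y-linked genes Eif2s3y and Uty rose, from 4.53 RPKM at P3 to 15.1 at P7 and from 0.577 to 1.79 (slopes 0.30 and 0.20), and 3 Y-linked genes rose when adjusted over the list alone (camera adjusted p = 0.168; median slope 0.20, mean -0.12). These calls were not robust to leaving out a library: Xist had an adjusted p of 0.0589 without P1 and 0.0515 without P14, Eif2s3y 0.104, 0.103 and 0.0670 without P1, P14 and P28, and Uty 0.0698 to 0.151 without E16.5, P1, P3 or P14. Reads of Xist and its antisense gene Tsix cannot be told apart without strand. The same step held large differences in Grm6 and Mki67.

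From first to last age, 1725 genes were higher at P28 than at E16.5 and 3351 lower, by at least 1 on the log2(RPKM + 1) scale, among 14596 genes at 1 RPKM or more at either age. Median-of-ratios rescaling gave 2271 higher and 2495 lower, and the common total gave 2510 and 2095. Among the genes with the largest gain were Gnat1 (log2 difference 7.44), Prph2 (6.94), Guca1a (6.91) and Pde6a (6.65). Among those with the largest loss were Tubb2a-ps2 (-5.41), Ndufa4l2 (-5.39), a mitochondrial protein induced by low oxygen, Tubb2b (-5.29), Ccnd1 (-5.25) and Fgf15 (-4.95). The median difference was 5.83 over the rod list, 2.81 over the bipolar list, 2.80 over the visual cycle list and 2.18 over the cone list, each at percentile 100 of 10000 random lists matched on expression. It was -3.26 over the cell cycle list, -2.76 over the progenitor list and -2.18 over the ganglion cell list, each at percentile 0. The thyroid hormone list had a median of 0.02, at percentile 92.7. These are differences between 2 libraries with no replicate check.

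The steps between neighbouring ages differed in size and in the genes that led them. Between E16.5 and P1, 160 genes were higher and 341 lower (200 and 212 with the common total). The rod factor Nr2e3 went from 0.708 to 17.4 RPKM, the photoreceptor transcriptional regulator Samd7 from 0.390 to 9.94 and Opn1sw from 4.03 to 35.3, while the globins Hba-a1, Hba-a2, Beta-s and Hbb-b1 were lower, with log2 differences of -5.72 to -4.10. Between P1 and P3, 297 genes were higher and 537 lower (443 and 401 with the common total). Ptprz1, a receptor phosphatase, went from 55.9 to 389 RPKM, Cdr1 from 1.83 to 17.6 and Ramp2, a receptor activity modifier, from 69.3 to 419.6. The ribosomal protein genes Rpl28, Rpl19 and Rps3a went from 18.3 to 0, from 21.1 to 0.492 and from 62.1 to 4.01 RPKM, a step that coincided with the change in title form, and many such genes have near-identical pseudogenes, so their values are uncertain.

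Between P3 and P7, 361 genes were higher and 540 lower. Grm6 and the calcium-binding protein Scgn were among the largest gains, with log2 differences of 4.69 and 3.24. Xist, Tsix, Mki67 and Top2a led the losses, with -6.57, -5.58, -3.88 and -3.69. For Xist and Tsix, age and the sex of the mice cannot be told apart. Between P7 and P14, the interval in which mice open their eyes, 446 genes were higher and 366 lower (598 and 265 with median-of-ratios rescaling). Gnat1 went from 35.9 to 2039 RPKM, the dopamine receptor Drd4 from 1.09 to 71.8 and the guanylate cyclase activator Guca1b from 2.35 to 59.2, while Cd24a, a surface protein of immature neurons, the fatty acid binding protein Fabp7 and the RNA-binding protein Mex3a were lower, with log2 differences of -3.02, -2.94 and -2.94. Between P14 and P28, 181 genes were higher and 81 lower. Cryaa, Fgf15, the ribosomal protein gene Rps23 and Atoh7 led the gains, with log2 differences of 4.003, 2.62, 2.37 and 2.21, and each of these was also present at E16.5. Cryaa was close to its E16.5 level, at 20.7 RPKM at P28 against 23.7. The lens list was higher at P28 than at P14 by a median of 0.94 log2 units (percentile 100). Klk1b22, Psd2, Igfbp7 and the endothelial junction gene Cldn5 led the losses, with -2.39, -2.06, -1.86 and -1.72. Like the step from P1 to P3, the step from P14 to P28 crossed a change in title form. For all genes named in either step, age and title form cannot be told apart.

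**Figure D4:**
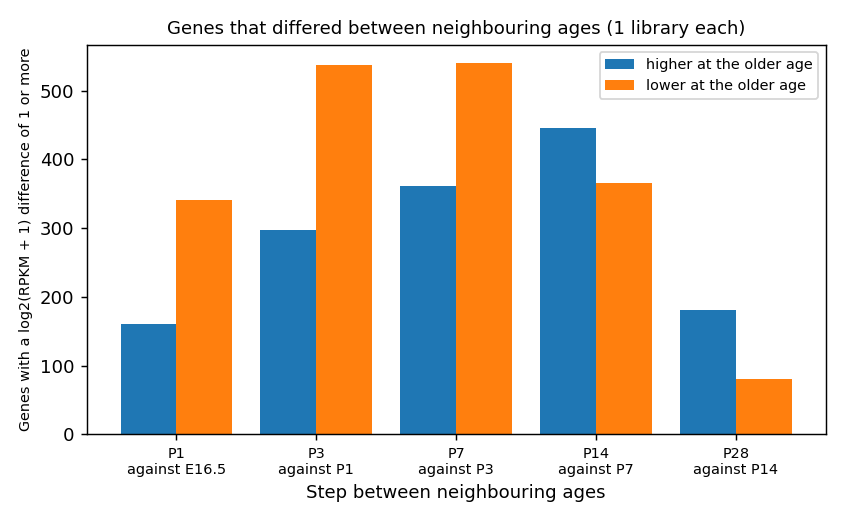
Number of genes whose log2(RPKM + 1) was higher or lower by 1 or more at the older of each pair of neighbouring ages, with 1 library per age. The count of higher genes was largest between P7 and P14 (446), and the count of lower genes was 537 between P1 and P3 and 540 between P3 and P7.

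The test for curvature asked which genes bent away from a straight line over the ages. Such genes can be highest or lowest in the middle of the series, or can level off or change late. It called 0 genes with limma, with 2858 at an unadjusted p under 0.05 (1652 with a negative and 1206 with a positive coefficient), and the lowest adjusted p was 0.0822. The most negative coefficients belonged to Nr2e3 (-3.55), which went from 0.708 RPKM at E16.5 to 192 at P7 and 58.1 at P28, and to Arhgap31, Samd7, Lrp4, Klk1b22 and Kif19a (-2.75 to -2.66). The most positive were those of Cryaa (4.46), Gnat1 (3.46), Atoh7 (3.45), Hba-a1 (3.37), Hba-a2 (3.20) and Fgf15 (2.84). Dio3 had a coefficient of 1.91 with an unadjusted p of 9.84e-06, and Crym, named with the thyroid hormone list, had -2.57 with an unadjusted p of 0.000198.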

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

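The title-form term and the E16.5 subtraction were added after the data were seen; the other alternatives were planned, and a test on whole reads was planned and not run, because whole reads were recovered for only part of the genes. No paired analysis was possible because each age has 1 library and no replicate number links libraries of different ages. The balance of gene counts changed direction with the scaling: with the common total more genes rose with age (3272) than fell (2720), more were higher at P28 than at E16.5 (2510) than lower (2095), and more were higher at P3 than at P1 (443) than lower (401), each the reverse of the values as deposited. Among repeated slopes and exact Spearman tests of the named genes, 2384 stayed on their side of the threshold, 229 lost their call and 22 gained one. Of the lost calls, 94 came from the exact Spearman test. Among slopes called in the main fit, 0 were counted as changed in direction. A change of sign in genes without a call, such as Crym, was not counted. The cause of the changes below was not tested unless stated.

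For the age trend, the 5 RPKM filter gave 1403 genes that rose, as fewer genes were tested, and the common total gave 2720 that fell. The exact Spearman test gave 407 and 908, because with 6 libraries it can call only genes with rho of 1 or -1; for the same reason it called 2 thyroid hormone genes, and gave Dio3 rho -0.83 (adjusted p = 0.128). Leaving out each age gave 1538 (without P14) to 2179 genes that rose and 2953 (without P14) to 4247 that fell. With the title term 2414 rose and 4819 fell, and after the E16.5 subtraction 2310 and 4796. Curvature stayed at 0 calls in all 7 alternatives run, and with an estimated correlation 0 lists were called.

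Between E16.5 and P28, a pseudocount of 5 gave 687 higher and 1568 lower, the 5 RPKM filter 1084 higher, the common total 2095 lower, and a size rule of 2 gave 537 and 900. In the order of the 5 steps, genes past the size rule numbered 1074, 1568, 1502, 1568 and 629 with a pseudocount of 0.1, 141, 299, 321, 283 and 46 with 5, and 35, 94, 181, 102 and 23 with a size rule of 2; the 5 RPKM filter left 133 for the last step. With that filter the first 4 steps kept 368, 635, 617 and 597 genes, of 501, 834, 901 and 812, but the filter acts on a gene's highest value, so how far the counts rest on low values stays open.

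The slope of Dio2 was 1.30 with a pseudocount of 0.1 and 0.32 with 5, and that of Dio3 -0.96 and -0.34, because both genes have values below 1 RPKM, which the pseudocount compresses. Over the libraries left out the slope of Dio2 ranged from 0.63 to 0.91 and that of Dio3 from -0.97 to -0.36 (adjusted p = 0.136 without E16.5); with age in log2 days the slope of Dio3 was -1.92 (adjusted p = 0.0744). The correlation of Dio2 ranged from 0.80 to 0.94 over the libraries left out and missed the threshold without P3 (r = 0.90, exact p = 0.0667). That of Dio3 ranged from -0.94 to -0.67 and kept an exact permutation p under the threshold only without P28; it was -0.80 with a pseudocount of 0.1 (exact p = 0.0528) and -0.80 with median-of-ratios rescaling (exact p = 0.05).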

Other observations

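The tests of the E16.5 traces at P28, of the title forms, of the sex markers and of the order of the ages were chosen after the results they bear on had been seen; the tests on hypoxia genes and on imprinted genes were written down before the values of those genes were looked at, and their lists and those for cilium and immediate early genes were added after the data were first examined.

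Genes of the photoreceptor connecting cilium, the stalk that joins the inner and outer segments, rose in 10 of 19 tested cases and fell in 1, with the same counts when adjusted over the list alone. Rp1l1, a microtubule-binding protein of the cilium, rose from 2.30 RPKM at E16.5 to 80.8 at P28 (slope 1.07, adjusted p = 0.00161), Tulp1 from 5.56 to 96.0 and Unc119, a carrier of lipid-anchored proteins, from 15.9 to 311, while the transport motor Kif3a fell from 22.5 to 8.95 (adjusted p = 0.00605). The median difference of this list between E16.5 and P28 was 1.05 log2 units, at percentile 100 of matched random lists. Of 9 tested immediate early genes 4 rose, also when adjusted over the list alone: Fos from 0.293 to 7.61 RPKM, Egr1 from 0.825 to 9.93, Junb from 1.76 to 4.57 and Nr4a1 from 3.94 to 12.3. Jun and Btg2, which did not pass the test, were at 30.9 and 33.9 RPKM at E16.5 and at 11.4 and 18.1 at P28. The list as a whole did not shift, with a median difference of -0.33 at percentile 46.2. These genes respond within minutes to handling of tissue, and the time from death to lysis is not given in the sources used here.

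Dio3 is an imprinted gene at the end of the Dlk1-Dio3 domain, so its fall could follow the domain or imprinted genes as a class. The other 5 tested genes of the domain had a median difference of 0.01 log2 units between E16.5 and P28, at percentile 77.1 of matched random lists, and 0 of them were called; Meg3 was at 61.8 and 82.3 RPKM and Mirg at 1.81 and 1.84, while Begain was at 38.7 and 20.1 and Rian at 12.8 and 8.46. The members moved in different directions, so a common fall of these 5 genes was not seen. Dlk1 was not among the tested genes, and Rtl1 stayed between 0.815 and 1.36 RPKM, where the log2 scale understates changes. A fall shared by Dio3 and only part of the domain could therefore be missed. Of 14 imprinted genes elsewhere in the genome 13 fell, with 13 that fell and 1 that rose when adjusted over the list alone, and a median difference of -1.63 at percentile 0.03. Plagl1 fell from 202 to 6.30 RPKM, H19 from 96.3 to 2.77, Nnat from 305 to 15.0 and Cdkn1c from 95.4 to 6.42, while Peg3, which did not pass over all genes, was at 14.7 and 29.7. The hypothesis that Dio3 falls with a wider set of imprinted growth genes is consistent with this percentile, but many of these genes are also expressed in dividing progenitors, and the list does not separate these readings.

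Glycolysis genes were lower at P1 than the mean of E16.5 and P3 in 17 of 19 cases, with a median of -0.43 log2 units. In 13 cases P1 was lower than both of these ages. The 17 include Gapdh, Pgk1 and Pgam1, whose low values are uncertain. A candidate explanation is a weaker hypoxia response in the P1 retinas. Genes known to respond to low oxygen, none of them in the glycolysis list, were lower at P1 than the mean of E16.5 and P3 in 16 of 16 cases, with a median of -0.75, at percentile 0 of 10000 matched random lists, and lower than at both ages in 12. Ddit4 was at 67.4, 16.1 and 49.95 RPKM at E16.5, P1 and P3, Vegfa at 49.4, 24.3 and 46.1, and Pdk1 at 12.2, 2.89 and 8.11. Immediate early genes were also lower at P1 than the mean of E16.5 and P3, in 8 of 9 cases with a median of -0.21 at percentile 4.89. The P1 library alone carries this dip, so oxygen supply in the newborn eye and the time the tissue spent without blood before lysis cannot be separated.

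The P28 library held low values of many transcripts that were high at E16.5, called a trace here, and their source is not settled. All 39 genes at 10 RPKM or more at E16.5 and at no more than 1% of that at P14 were higher at P28 than at P14, by a median of 2.21% of the E16.5 value (quartiles 1.81% and 2.87%), and 111 of 114 genes in a wider set were, by 2.03%. Picking genes for a low P14 value favours a higher P28 value, so the sign alone carries little weight. The 39 genes include the sex marker Xist (1.36%), the ribosomal genes Rpl19 (10.2%) and Rpl28 (9.46%) and the lens gene Crybb1 (31.1%), so they are not a uniform set. In a fit of the P28 excess on both early libraries, E16.5 received a weight of 1.77% and P1 a weight of 0%. The fit was unweighted, so genes with the highest values count most. The trace may also run the other way, through mixing of the E16.5 and P28 libraries as RNA, library or reads. Of 12 genes at 5 RPKM or more at P28 and at no more than 2% of that at P7, 10 held a larger share of their P28 value at E16.5 than at P3 and 2 did not, with medians of 0.661% at E16.5, 0.642% at P1 and 0.331% at P3. This reading is the weaker one: the pattern was found in single photoreceptor genes first, and not in all of those looked at, several floors of expression were tried before 5 RPKM, the bound for the share of genes was written after the values were seen, P1 shows nearly the same median as E16.5, and the set includes the lens gene Cryaa, which was higher at E16.5 than at P28. Cells that keep embryonic transcripts until P28 were predicted to leave a much smaller share in genes already low at P1; these held 1.01 times the share of genes still high at P1 (4 and 22 genes), so that prediction was not met. The explanation stays open only because 1 library per age confounds cells with library and 4 genes are few. If the trace came from E16.5 material, it bears on Dio3. The P14 value of Dio3 plus the median share predicts 0.560 RPKM at P28. Measured were 0.834 RPKM, whose 95% counting interval of 0.510 to 1.29 holds the prediction. Dio3 was not among the 39 genes, and its own share of 3.91% lay above their upper quartile of 2.87%.

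Some genes followed the form of the library title rather than age. Beside the age slope, 87 genes were called for the title sets (77 higher in E16.5, P1 and P28, and 10 lower), against at most 9 for the other splits into 3 and 3; the real split was 1 of 10, too few for a share under 0.05. At an unadjusted p under 0.05 it gave 2215 genes, fewer than the 2515 of the split with E16.5, P14 and P28 on one side. Ribosomal protein genes were higher in E16.5, P1 and P28 in 77.3% of 75 cases, against 44.1% of all genes, and in 81.3% and 72.0% with median-of-ratios and common-total rescaling. A batch of libraries or of their processing may be the source. The bound of 80% set for it was written after the values were seen. The share passed that bound only with median-of-ratios rescaling, so the bound does not decide for or against a batch. Age and batch cannot be told apart for these genes. Depth argues the other way, because the libraries with lower ribosomal values were the deeper ones, with 1.90 times the reads.

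The shift of Xist and of Y-linked genes between P3 and P7 may reflect more male animals at P7, P14 and P28. All 4 Y-linked genes were higher in each of these than in each earlier library, by 1.87-fold (Kdm5d) to 3.62-fold (Uty), where chance gives 5% and 18.4% of all tested genes showed the same order; Xist was 108-fold higher in the earlier libraries. Loss of Xist with age in female cells would leave the Y-linked genes at their level. Their median log2 shift was 0.93, which argues against loss of Xist alone as the source. A difference of sex may therefore run along the age series, in which case age and sex are confounded for genes that differ between the sexes.

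The number of genes called for the age trend, 6897, was larger than under every other order tried. Of 100 orders of the ages 1, the real one, reached that number, and the highest other order gave 3578. That other order was close to the real one reversed (Spearman's rho -0.94 with the real order), and only 2 of the other orders gave any call. The comparison cannot tell age from anything else that ran along the series, such as the sex of the mice.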
